A study of Mus musculus with 80 samples.

How the data were processed

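The series measured RNA of T cells from mouse lung, sorted as CD69+ or CD69-, from HDM-sensitised and naive mice. Per the series description, sensitisation was by 20 µg HDM with 2 mg alum into the peritoneum and each challenge by 10 µg HDM into the nose, and an antibody to CD90.2 injected before tissue collection marked cells in the vessels. Cells protected from it are termed extravascular. The labels state no sort on CD4, which the title names. The description gives days 45 and 47 for sequencing and 4 weeks of rest after day 24, while the labels hold 8 days from 21 to 48, and the 10 libraries labelled day 46 carry titles that read day 45. The labels' days were used. Whether a day's libraries were taken before or after that day's dose is not stated.

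Per the labels, total RNA was extracted with the miRNeasy micro kit and made into Nextera XT libraries, with 1 column of counts per sample. The authors deposited raw counts per gene (unit: counts, with no normalization), whole numbers under Ensembl gene identifiers with symbols. Per the submitters' processing notes the tools were Bowtie 1.0.0, STAR 2.6.1 and featureCounts 1.6.5 with build GRCm38. The role of each aligner, the strand setting and the annotation release are not stated. Gene positions were taken from GENCODE release M21, in which 13477 of the 13508 kept identifiers were found.

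The table had 47729 genes, of which 24131 had at least 1 count. Totals ranged from 890699 to 23033457 per library (median 6250300.5), and 5213 to 14562 genes were detected per library. Sequencing reads carry no molecular identifiers, so counts are not independent molecules. The groups were the 32 combinations of day, HDM or naive status and CD69 gate, with 3 libraries per HDM and 2 per naive group. No library was left out of the tests unless stated. Day 45 held 3 libraries with fewer than 9000 detected genes, namely HDM CD69+ replicate 1 (7407), naive CD69- replicate 2 (8813) and naive CD69+ replicate 2 (5213). The highest correlation between 2 libraries was 0.885, and at most 44.5% of genes had equal counts in 2 libraries, so none was a copy of another.

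Genes were kept when at least 8 libraries reached the CPM that 10 counts make in the library of median size, which left 13508 genes with 99.8% of the counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16, by TMM factors, a model with a mean for each of the 32 groups, and robust quasi-likelihood F tests. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons averaged the within-day differences over the 8 days: CD69+ against CD69- cells in HDM mice, in naive mice and the difference of these, and HDM against naive in CD69+ and in CD69- cells. The HDM difference was then compared between the 4 tertiary and the 4 secondary days, between days 24 and 21, 48 and 45, and 45 and 21, and tested within each day in CD69+ cells. Each SE is the log2 fold change over the square root of its F. Mean CPM and SD were computed over the libraries of a group from TMM-scaled totals, and log2 CPM with a prior count of 2. Differences in library measures between HDM and naive libraries were tested by two-sided permutation tests with 100000 permutations.

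The 32 gene lists (18 of T-cell states, 14 of other cell types) were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and beside it an estimated correlation, and with fry. Adjustment was over the lists and the 7 comparisons averaged over days. Counts of list members are given over all genes tested and adjusted over the list alone.

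The sample groups, comparisons, filter, test, gene lists, alternatives and the rule for named genes were set before the data were examined. By that rule the text names the 10 highest and 10 lowest genes of each comparison averaged over days, or 5 and 5 between single days, among those past the threshold with a mean log2 CPM of at least 3 and, where 8 days were averaged, the same sign on at least 7. Variable, diversity and joining segments of immune receptors and unnamed genes were excluded. Cd69, the genes of the title and up to 4 members of each described list with the smallest p were added. The text leaves out some genes of unclear function and, by a choice made after the data were seen, those with a compared group whose libraries were all at 0, because their fitted fold depends on the prior count. For the same reason Il13, Il5 and Tnfrsf8 are given as levels where that applies, and Lag3 and Cxcr5 between days are given with levels because some of their libraries lay near 0. The text names 75 different genes.

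The test was checked on simulated counts that kept the design, library totals and the trend of dispersion, with 100 genes changed by each fold. Unchanged genes had the same expected share in every library. Dispersions of single genes and the libraries with few detected genes were therefore not reproduced. The shares of calls on unchanged genes depend on the number of genes changed and are not those of the real comparisons. For CD69+ against CD69- cells in HDM mice, 15% of genes changed by 2-fold and 49% of those changed by 4-fold were called, and 26.9% of the 93 calls fell on unchanged genes. For HDM against naive CD69+ cells the values were 10%, 51% and 25.6% of 90 calls. Among genes with no compared group at 0 in all its libraries, 7.04% of 71 and 3.12% of 64 calls fell on unchanged genes. Unchanged genes with such a group had an unadjusted p under 0.05 in 16.8% and 18.8% of cases, against 5.53% and 5.95% for the others. Counts are therefore also given among genes with at least 1 count in every compared group, which was added after the data were seen. For day 48 alone, 7% of genes changed by 4-fold and 25% of those changed by 16-fold were called, with 2.94% of 34 calls on unchanged genes.

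The alternatives set beforehand were DESeq2 1.42.0, limma-voom, RLE factors, no filter, the filterByExpr filter, a threshold with an absolute log2 fold change of at least 1, a block for consecutive title numbers, a fit to the compared groups alone, no subtraction of naive libraries, leaving out each day and leaving out each library. Added after the data were seen were fits without the 3 libraries with few detected genes, without genes at 0 in a compared group, with an additive term for day and with the number of detected genes as a covariate. Fits without a day or library, and those of regrouped libraries, reused the dispersion trend of all 80 libraries, and a lone library in a group was assumed to vary like the others. Whether libraries of consecutive title numbers came from the same mice is not stated, so pairs were used in a check alone.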

Results

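The deposited table held counts of 80 RNA libraries from mouse lung T cells, named Tissue-resident memory T cells in the labels and sorted as CD69+ or CD69-. CD69 is a surface protein that holds T cells in tissue by removing the exit receptor S1PR1 from the membrane. Cells came from naive mice and from mice sensitised to house dust mite (HDM), an allergen used to model asthma. The labels gave 8 days, of which days 21 to 24 belonged to a secondary and days 45 to 48 to a tertiary intranasal exposure. Each day had 3 HDM and 2 naive libraries per gate, or 24 CD69+ and 24 CD69- libraries of HDM mice and 16 and 16 of naive mice. Totals ran from 890699 to 23033457 counts per library, and 13508 genes were tested. The labels did not state whether replicates were separate animals, so p-values measured the spread between samples, which may be technical. Levels are CPM (counts scaled to a library total of 1e6) as mean ± SD over the libraries named, and differences are log2 fold changes ± SE.

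CD69+ cells of HDM mice carried more RNA of the type 2 cytokines IL-13 and IL-5 and of the receptors OX40 and 4-1BB than CD69- cells. Ccl1, which encodes a chemokine made by activated T cells, was 3.19 ± 0.32 higher (330 ± 278 against 37.9 ± 26 CPM, adjusted p = 4.07e-10). Il13 and Il5 encode cytokines that drive mucus and eosinophils, and lie on chromosome 11 of GRCm38 (53631324 to 53634702 and 53720794 to 53725106). Il13 was 2.58 ± 0.39 higher (147 ± 114 against 27.8 ± 32.6 CPM, adjusted p = 1.03e-05) and Il5 2.51 ± 0.46 higher (501 ± 401 against 90.4 ± 76.6 CPM, adjusted p = 0.000215). Penk, which encodes an opioid precursor, was 2.84 ± 0.35 higher (adjusted p = 7.85e-08) and Ptprs, a phosphatase gene, 1.82 ± 0.43 higher (adjusted p = 0.00527). The costimulatory receptor genes Tnfrsf4 (OX40, chromosome 4, 156013843 to 156016612) and Tnfrsf9 (4-1BB) were 1.03 ± 0.10 (1950 ± 1010 against 845 ± 323 CPM, adjusted p = 3.16e-10) and 1.69 ± 0.19 higher (adjusted p = 3.85e-09). Each of these genes was higher on 8 of 8 days, except Tnfrsf4, which was higher on 7. Ptprs missed the threshold without the libraries of day 46 (adjusted p = 0.073) and with a block for consecutive title numbers (adjusted p = 0.061).

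Genes of lymph node homing and tissue exit were lower in the CD69+ cells of HDM mice. Klf2, a transcription factor gene that keeps T cells circulating (ENSMUSG00000055148.7, chromosome 8, 72319033 to 72321656), was -2.64 ± 0.16 (64.7 ± 44.9 against 358 ± 165 CPM, adjusted p = 5.85e-19). Its target S1pr1 (chromosome 3, 115710433 to 115715072), which encodes the receptor for exit towards blood and lymph, was -3.05 ± 0.29 (71 ± 51 against 451 ± 201 CPM, adjusted p = 6.24e-11). Cd7, a surface receptor gene of T and NK cells, was -3.27 ± 0.61 (adjusted p = 0.000262), and Slamf6, a receptor gene of less differentiated T cells, -1.77 ± 0.21 (adjusted p = 1.86e-08). Cd69 itself differed by 0.16 ± 0.11 (887 ± 188 against 796 ± 221 CPM, adjusted p = 0.686). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 496 genes passed 0.05, of which 122 were higher and 374 lower. Tested and adjusted among genes with at least 1 count in every compared group, 303 passed (99 higher, 204 lower). DESeq2 called 1630 and limma-voom 1028 of all genes. On simulated data with the same design, 26.9% of the calls fell on unchanged genes, against 7.04% among genes with at least 1 count in every compared group. These shares depend on how many genes were changed in the simulation and are not those of the real calls.

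**Figure D1:**
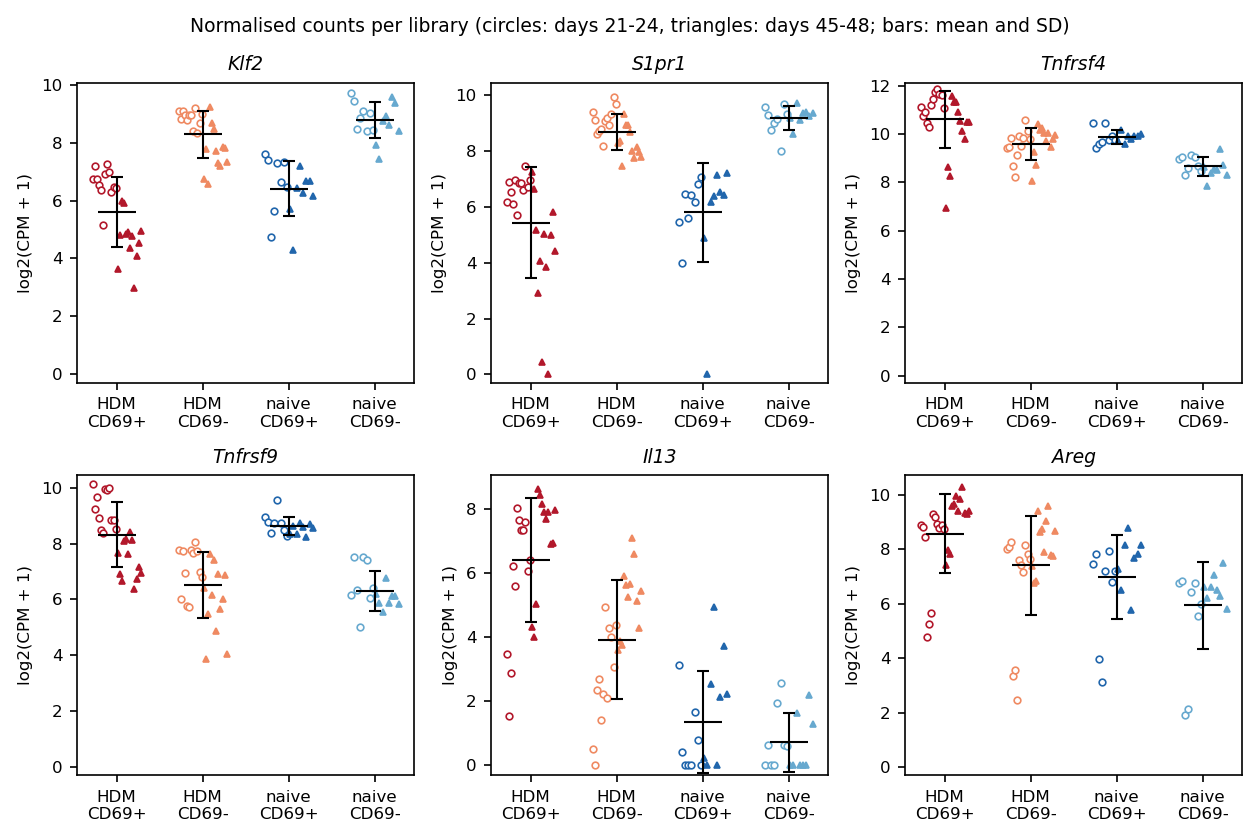
Level of 6 genes in each of the 80 libraries, as log2 of CPM + 1, by gate and mouse status, with circles for days 21 to 24, triangles for days 45 to 48, and bars for mean ± SD. Klf2 and S1pr1 were lower in CD69+ libraries of both HDM and naive mice, while Il13 averaged 147 CPM in HDM CD69+ and 4.07 CPM in naive CD69+ libraries.

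Several lists of genes, set before the data were examined, moved together in this comparison. In the recirculation list, 11 of 16 genes were lower over all genes tested and 15 adjusted over the list alone, with S1pr4, another receptor gene of the same lipid, at -0.85 ± 0.12 (adjusted p = 3.73e-06). The list passed limma's camera test at an adjusted p of 7.1e-09 with an estimated correlation. Of 14 naive and central memory genes, 9 were lower (11 adjusted over the list alone, adjusted p = 5.7e-09 with an estimated correlation). Among them were the survival receptor gene Il7r at -1.20 ± 0.16 (adjusted p = 3.47e-07) and the memory factor gene Tcf7 at -1.05 ± 0.16 (adjusted p = 4.15e-06). Of 18 type 2 helper genes, 7 were higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 4.7e-05 with an estimated correlation). They included the epithelial growth factor gene Areg at 1.14 ± 0.13 (adjusted p = 9.03e-09) and the chemokine receptor gene Ccr8 at 1.19 ± 0.17 (adjusted p = 2.1e-06). Of 16 regulatory T-cell genes, 6 were higher (7 higher and 1 lower adjusted over the list alone, adjusted p = 7.1e-05 with an estimated correlation). Il2ra, an IL-2 receptor gene, was at 1.03 ± 0.15 (adjusted p = 1.85e-06) and the inhibitory receptor gene Ctla4 at 0.72 ± 0.11 (adjusted p = 3.67e-06). The costimulatory list had 3 of 14 genes higher (3 adjusted over the list alone, adjusted p = 0.019 with an estimated correlation), the 6 genes of the title 1 (2 adjusted over the list alone, adjusted p = 0.032) and 5 marker genes of group 2 innate lymphoid cells 2 (2 adjusted over the list alone, adjusted p = 0.011). In the tissue residency list, 4 of 21 genes were higher and 1 lower, and the same counts held adjusted over the list alone. Among them were the lung homing receptor gene Cxcr6 at 0.63 ± 0.13 (adjusted p = 0.00162) and the residency factor gene Bhlhe40 at 0.61 ± 0.10 (adjusted p = 1.96e-05). The list passed with the preset correlation (adjusted p = 0.00035) but not with the estimate (adjusted p = 0.072 with an estimated correlation). The type 1 and cytotoxic list moved both ways, with 2 of 19 genes higher and 4 lower (2 and 5 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation). Its chemokine gene Ccl5 was -1.23 ± 0.17 (adjusted p = 1.18e-06).

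CD69+ and CD69- cells of naive mice differed in many of the same genes. Klf2 was -2.37 ± 0.19 (99.8 ± 52.6 against 477 ± 190 CPM, n = 16 and 16, adjusted p = 2.3e-13), S1pr1 -3.20 ± 0.36 (adjusted p = 4.75e-09) and Rasgrp2, a gene of integrin activation, -2.36 ± 0.48 (adjusted p = 0.00184). Tnfrsf9 was 2.30 ± 0.23 higher (407 ± 110 against 88 ± 48.9 CPM, adjusted p = 3.51e-10), Tnfrsf4 1.22 ± 0.13 (958 ± 206 against 417 ± 111 CPM, adjusted p = 7.48e-10) and Penk 2.71 ± 0.42 (adjusted p = 2.53e-05). Fgl2, which encodes a suppressive effector of regulatory T cells, was 2.07 ± 0.23 higher (adjusted p = 4.75e-09), and Klrg1, a receptor gene of differentiated cells, 1.73 ± 0.20 (adjusted p = 1.07e-08). Cd83, an activation gene, was 1.73 ± 0.34 higher (adjusted p = 0.000995) and Mmp9, a matrix protease gene, 2.56 ± 0.69 (adjusted p = 0.036). Pxdc1, a gene of little known function, was -2.53 ± 0.44 (66 ± 39.6 against 371 ± 221 CPM, adjusted p = 0.000163), and Dtx1, a Notch pathway gene, -2.63 ± 0.66 (adjusted p = 0.0176). In total 238 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (60 higher, 178 lower). Tested and adjusted among genes with at least 1 count in every compared group, 187 passed (51 higher, 136 lower). DESeq2 called 1050 and limma-voom 974. Without day 45 naive CD69+ replicate 1, which leaves a library of 5213 detected genes alone in its group, the count was 2763 and Mmp9 stood at 1.0. Without day 45 naive CD69- replicate 1 it was 382. Mmp9 missed the threshold in 22 and Dtx1 in 8 of the 32 fits that left out 1 library.

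The regulatory T-cell list was higher in the naive CD69+ cells too, with 6 of 16 genes over all genes tested and 8 adjusted over the list alone (adjusted p = 1.4e-05 with an estimated correlation). Its lineage factor gene Foxp3 was 1.51 ± 0.28 higher (adjusted p = 0.000373), Il2ra 1.04 ± 0.18 (adjusted p = 0.000147) and Ctla4 0.46 ± 0.13 (adjusted p = 0.0429). The tissue residency list passed here, with 3 of 21 genes higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0073 with an estimated correlation). The recirculation list had 4 of 16 genes lower (12 adjusted over the list alone, adjusted p = 1.1e-06 with an estimated correlation), and the type 17 list had 3 of 12 lower (5 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation). The costimulatory list had 4 of 14 genes higher and 1 lower (4 and 2 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation). Ctla4 missed the threshold with limma-voom (adjusted p = 0.109) and in 18 of the 32 fits that left out 1 library.

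Of the genes called in both CD69 comparisons, 116 of 117 had the same sign, 34 higher and 82 lower, where chance would give 0.542 and 4.93. Across 7048 genes with a mean log2 CPM of at least 3, the differences in HDM and naive mice correlated with Pearson's r of 0.32 (jackknife SE 0.17) and Spearman's rho of 0.24. The comparisons shared no library, and genes are not independent replicates. The CD69 difference itself differed between HDM and naive mice for 10 genes (3 higher, 7 lower in HDM mice) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ramp1, part of the receptor of the neuropeptide CGRP, differed most clearly (1.48 ± 0.21, adjusted p = 4.42e-05). It was higher in CD69+ than in CD69- cells of HDM mice (364 ± 152 against 210 ± 97.1 CPM) and lower in those of naive mice (331 ± 89 against 539 ± 204 CPM). Pxdc1 gave 2.45 ± 0.54, and Malat1, a nuclear RNA, -0.99 ± 0.22 (both adjusted p = 0.0477). With an additive day term both missed the threshold (adjusted p = 0.126 and 0.587), while Ramp1 passed (0.00384). Regroupings of the libraries gave up to 113 genes, and 1613 passed without day 45 naive CD69+ replicate 1. Among the 8 genes named from this comparison, Ramp1 alone held in each fit that left out 1 library.

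Type 2 cytokine genes were higher in HDM than in naive CD69+ cells. Il13 averaged 147 ± 114 CPM in 24 HDM libraries and 4.07 ± 7.73 CPM in 16 naive libraries, and Il5 501 ± 401 and 32 ± 66.4 CPM. Both had a day on which no naive library held a count, so no fold is given, and both passed (adjusted p = 1.18e-11 and 1.22e-08). Il4, the gene of the cytokine that sets the type 2 fate (chromosome 11, 53602982 to 53618669), was 3.22 ± 0.39 higher (116 ± 78.5 against 11.8 ± 10.2 CPM, adjusted p = 2.32e-08), and Il1rl1, the IL-33 receptor gene, 1.75 ± 0.31 (adjusted p = 7.51e-05). Areg, a tissue repair gene, was 1.56 ± 0.15 higher (522 ± 312 against 177 ± 113 CPM, adjusted p = 3.58e-11). Ifitm3, an interferon-induced antiviral gene, was 3.65 ± 0.49 higher (171 ± 167 against 11 ± 11.3 CPM, adjusted p = 3.11e-07) and Lgmn, a lysosomal protease gene, 3.23 ± 0.43 (adjusted p = 2.11e-07). Each gene in these sentences was higher on 8 of 8 days. Rgs1, a brake on chemokine signals (chromosome 1, 144242296 to 144249242), was 1.45 ± 0.14 higher (2400 ± 2070 against 683 ± 323 CPM, adjusted p = 1.18e-11), but limma-voom put its adjusted p at 0.139.

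Some genes of type 1 cells and some immediate early genes were lower in the HDM CD69+ cells. Cxcr3, a homing receptor gene of type 1 cells, was -1.61 ± 0.11 (adjusted p = 3.76e-16), the cytotoxic granule gene Nkg7 -1.24 ± 0.16 (adjusted p = 1.27e-07) and Ccl5 -1.32 ± 0.19 (adjusted p = 7.01e-07). The immediate early gene Fos was -0.85 ± 0.09 (adjusted p = 2.62e-10) and Btg2, a growth brake induced with it, -0.88 ± 0.10 (adjusted p = 2.22e-09). Cd27, a costimulatory gene lost with differentiation, was -1.02 ± 0.20 (adjusted p = 0.000318), Trac, the constant gene of the alpha receptor chain, -0.42 ± 0.06 (adjusted p = 3.59e-06), and the follicular homing gene Cxcr5 -2.37 ± 0.44 (adjusted p = 0.000105). Cd69 was 0.60 ± 0.12 higher (adjusted p = 0.00038). Across genes, 1038 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (519 higher, 519 lower). Tested and adjusted among genes with at least 1 count in every compared group, 796 passed (457 higher, 339 lower). DESeq2 called 2464 and limma-voom 2475, and scaling by RLE factors gave 437 higher and 606 lower. Without day 45 naive CD69+ replicate 1 the count was 3218 and Cxcr5 stood at -0.81 (adjusted p = 1).

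Among the lists, type 2 genes had the smallest p, with 9 of 18 higher in HDM CD69+ cells (10 higher and 1 lower adjusted over the list alone, adjusted p = 4.7e-05 with an estimated correlation). Of 21 interferon response genes, 7 were higher (7 adjusted over the list alone, adjusted p = 0.01 with an estimated correlation). Ifi27l2a, an interferon-induced gene, was 1.24 ± 0.12 higher on average though on 6 of 8 days alone (adjusted p = 6.68e-11, limma-voom 0.131). Of 13 glycolysis genes, 5 were higher (7 adjusted over the list alone, adjusted p = 0.016 with an estimated correlation), led by the lactate enzyme gene Ldha at 0.94 ± 0.09 (adjusted p = 1.18e-11). Of 37 proliferation genes, 3 were higher (3 adjusted over the list alone, adjusted p = 0.034 with an estimated correlation). Immediate early genes had 2 of 32 higher and 17 lower (3 and 19 adjusted over the list alone, adjusted p = 0.049 with an estimated correlation). The type 1 and cytotoxic list had 8 of 19 lower (10 adjusted over the list alone) and missed the threshold (adjusted p = 0.073 with an estimated correlation). In the regulatory list Ctla4 was 0.91 ± 0.12 higher (adjusted p = 1.7e-07). Of 5 marker genes of group 2 innate lymphoid cells, 3 were higher (4 adjusted over the list alone, adjusted p = 0.016 with an estimated correlation), of which Il1rl1 is shared with the type 2 list. Whether such cells were among those sorted was not tested. The type 2 cytokine RNA therefore cannot be assigned to CD4 T cells alone.

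CD69- cells of HDM mice differed from those of naive mice in the same direction for many of these genes. Il5 was 3.55 ± 0.58 higher (90.4 ± 76.6 against 7.07 ± 9.59 CPM, n = 24 and 16, adjusted p = 4.53e-05), Il4 2.31 ± 0.38 (adjusted p = 3.52e-05), Il1rl1 2.56 ± 0.33 (adjusted p = 1.95e-07) and Areg 1.54 ± 0.15 (266 ± 195 against 83.2 ± 44.8 CPM, adjusted p = 2.85e-10). Interferon-induced genes were higher as well, with Usp18, a brake on the interferon receptor, at 3.25 ± 0.70 (adjusted p = 0.0026) and Ifitm3 at 2.56 ± 0.46 (adjusted p = 0.000237). Plac8, a gene of effector T cells, was 2.96 ± 0.40 higher (adjusted p = 6.8e-07), Rgs1 1.84 ± 0.14 (adjusted p = 1.38e-14, limma-voom 0.244) and Cd69 0.62 ± 0.12 (adjusted p = 0.000622). Pxdc1 was -2.51 ± 0.38 (adjusted p = 8.34e-06), Lmo4, a transcription cofactor gene, -2.20 ± 0.25 (adjusted p = 9.32e-09), Ckb, a creatine kinase gene, -1.92 ± 0.30 (adjusted p = 1.42e-05) and Il17rb, the IL-25 receptor gene, -2.30 ± 0.55 (adjusted p = 0.00813). Cxcr3 was -0.99 ± 0.11 (adjusted p = 8.3e-09), Fos -0.75 ± 0.09 (adjusted p = 1.44e-08) and Trac -0.29 ± 0.06 (adjusted p = 0.00245, 0.0921 without the libraries of day 48). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 437 genes passed, 256 higher and 181 lower. Tested and adjusted among genes with at least 1 count in every compared group, 363 passed (239 higher, 124 lower). DESeq2 called 1304 and limma-voom 867. Scaling by RLE factors moved the split to 215 higher and 240 lower. Without day 45 naive CD69- replicate 1 the count was 700.

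All 270 genes called in both the CD69+ and the CD69- comparison of HDM with naive mice had the same sign, 187 higher and 83 lower, where chance would give 9.84 and 6.95. Pearson's r across 7048 genes was 0.58 and Spearman's rho 0.56, from libraries that were not shared. CD69+ and CD69- libraries may come from the same mice, while the chance values assume independent comparisons. In CD69- cells, 6 of 18 type 2 genes were higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.00016 with an estimated correlation). Interferon response genes had 5 of 21 higher (13 adjusted over the list alone, adjusted p = 0.00013 with an estimated correlation) and proliferation genes 2 of 37 (adjusted p = 0.016 with an estimated correlation). The 5 marker genes of group 2 innate lymphoid cells had 2 higher (3 adjusted over the list alone, adjusted p = 0.028 with an estimated correlation). Immediate early genes had 1 of 32 higher and 11 lower (2 and 16 adjusted over the list alone) and missed the threshold (adjusted p = 0.072 with an estimated correlation). Of the 84 tests of a list that passed with the preset correlation, 36 held with an estimated correlation.

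**Figure D2:**
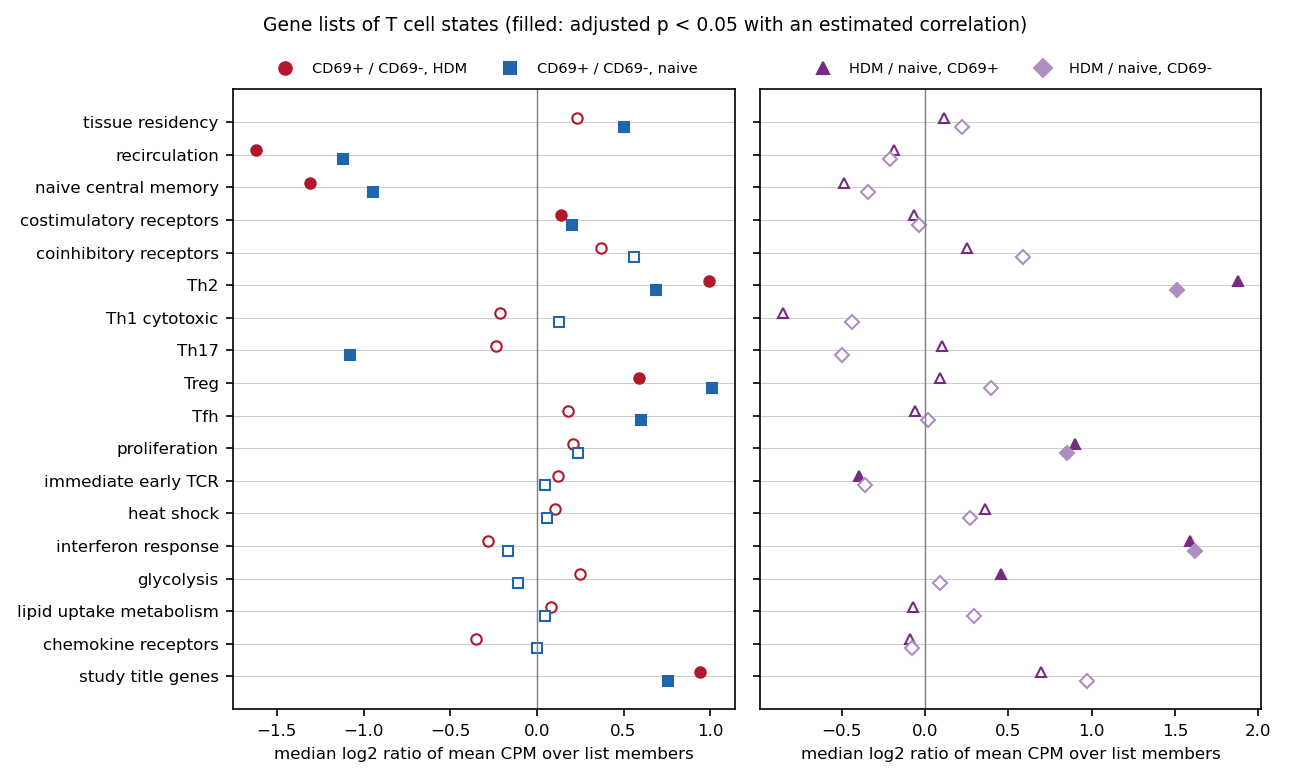
Median log2 ratio of mean CPM over the genes of each list, for CD69+ against CD69- cells in HDM and naive mice (left) and for HDM against naive mice in CD69+ and CD69- cells (right), with filled points where the adjusted p with an estimated correlation was under 0.05. The recirculation list lay at -1.62 in HDM mice, and the type 2 list at 1.88 for HDM against naive CD69+ cells.

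The series title names the ligands of ICOS (Icos), OX40 (Tnfrsf4) and CD30 (Tnfrsf8), receptors that sustain memory T cells. Tnfrsf4 was higher in HDM than in naive mice, by 0.75 ± 0.12 in CD69+ cells (7 of 8 days, adjusted p = 5.57e-06) and by 0.95 ± 0.12 in CD69- cells (8 of 8 days, adjusted p = 8.94e-08, limma-voom 0.13). Icos (chromosome 1, 60977927 to 61000320) was lower in HDM CD69- cells (-0.52 ± 0.11, 672 ± 262 against 953 ± 363 CPM, adjusted p = 0.0017), and in CD69+ cells its difference missed the threshold (-0.29 ± 0.11, adjusted p = 0.0996, 0.0167 with DESeq2). Between gates, Icos was -0.45 ± 0.12 in naive mice (adjusted p = 0.0329, 0.101 with RLE factors, and lost in 17 of the 32 fits that left out 1 library) and -0.22 ± 0.10 in HDM mice (adjusted p = 0.306). Tnfrsf8 (chromosome 4, 145267137 to 145315164) held 30.4 ± 25.2 CPM in HDM CD69+, 12.1 ± 13.9 in HDM CD69-, 17.5 ± 12.2 in naive CD69+ and 2.17 ± 4.3 in naive CD69- libraries. The naive CD69- libraries were at 0 on 4 days, and Tnfrsf8 passed in naive CD69+ against CD69- cells (adjusted p = 0.00182) and in HDM against naive CD69- cells (adjusted p = 0.00441), without a fold. Both missed the threshold with an additive day term (adjusted p = 0.145 and 0.308), the first also with a block for consecutive title numbers (0.099), and 2 of the 32 and 1 of the 40 fits that left out 1 library missed it too. Tnfsf8, which encodes CD30 ligand and is also made by T cells, was 1.06 ± 0.33 higher in HDM than naive CD69+ cells (356 ± 174 against 164 ± 81.3 CPM, adjusted p = 0.0372). In CD69- cells its difference of 0.83 ± 0.33 missed the threshold (adjusted p = 0.209), as did its gate differences in HDM (0.84 ± 0.29, adjusted p = 0.104) and naive mice (0.61 ± 0.35, adjusted p = 0.777). The gate difference in HDM mice passed with DESeq2 (adjusted p = 0.0171) and limma-voom (0.00155), the CD69- difference with limma-voom (0.00511), and all 3 without the libraries of day 45 (1.9e-06 for HDM mice, 0.0246 for naive mice, 0.00147 for CD69- cells). Icosl averaged 33.1 CPM and Tnfsf4 (OX40 ligand) 1.13 CPM in HDM CD69+ libraries, and neither passed in these comparisons. The Tnfsf8 difference in CD69+ cells missed the threshold in 13 of the 40 fits that left out 1 library, with edgeR's own filter (adjusted p = 0.0518), with the compared groups alone (0.0768) and without day 22, 23, 24, 46, 47 or 48. It was 2.61 (adjusted p = 1.37e-08) without day 45 naive CD69+ replicate 1.

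**Figure D3:**
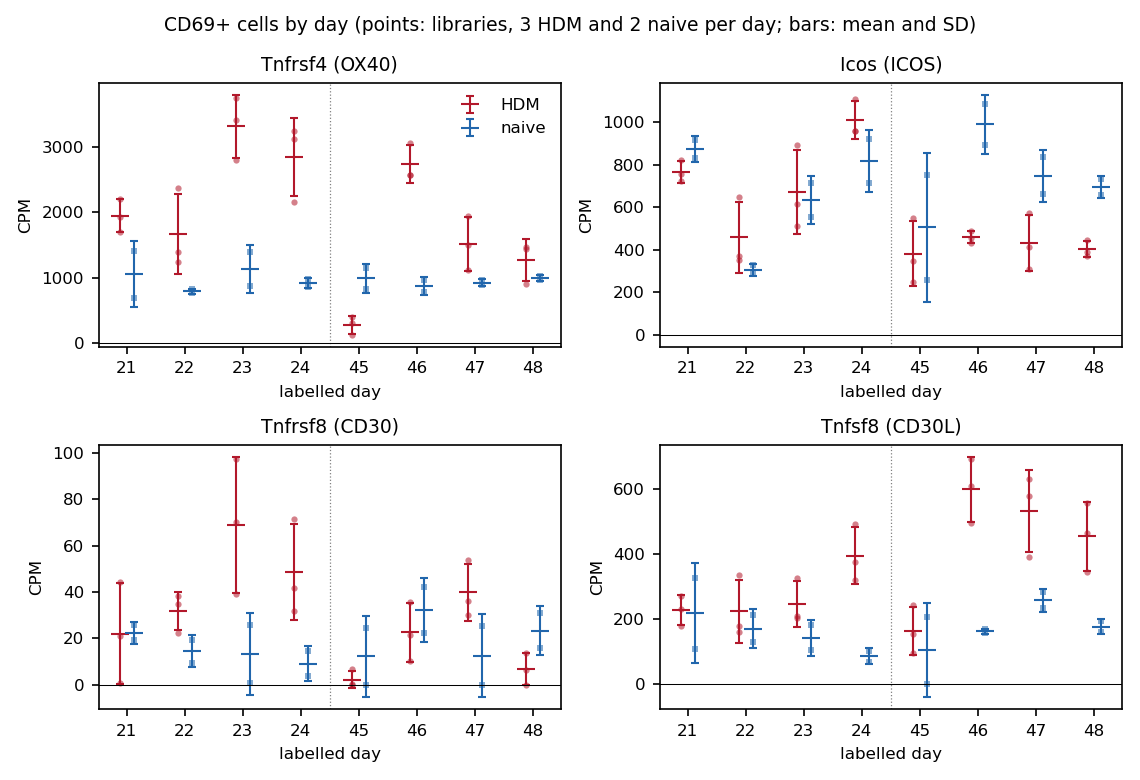
CPM of Tnfrsf4, Icos, Tnfrsf8 and Tnfsf8 in each CD69+ library by day, HDM and naive, with mean ± SD. Tnfrsf4 in HDM libraries ranged from a mean of 275 CPM on day 45 to 3320 CPM on day 23, and the day means of naive libraries lay between 791 and 1130 CPM.

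The difference between HDM and naive CD69+ cells was then compared between the tertiary and the secondary days. Rgs1 gained 1.66 ± 0.26 (adjusted p = 0.000199, limma-voom 0.53), as HDM libraries went from 983 ± 580 CPM on secondary days to 3810 ± 2060 on tertiary days (n = 12 each) and naive libraries from 628 ± 312 to 738 ± 345 (n = 8 each). Fgl2 gained 2.05 ± 0.41 (adjusted p = 0.00274), Il7r 1.74 ± 0.35 (adjusted p = 0.00311), Cxcr6 1.58 ± 0.30 (adjusted p = 0.00199) and Maf, a factor gene of cytokine expression, 1.42 ± 0.30 (adjusted p = 0.00492, 0.105 without a filter). Cxcr6 in HDM libraries was 739 ± 198 CPM on secondary and 1840 ± 508 CPM on tertiary days, and in naive libraries 937 ± 214 and 825 ± 368 CPM. Tnfrsf4 was -1.07 ± 0.23 (adjusted p = 0.00613, limma-voom 0.123) and Icos -0.97 ± 0.22 (adjusted p = 0.0119). The HDM difference of Tnfrsf4 was 0.89, 1.08, 1.55 and 1.63 on days 21 to 24 and -1.85, 1.65, 0.71 and 0.35 on days 45 to 48, so day 45 carried most of its value. The regulatory genes Foxp3 and Izumo1r (folate receptor 4) were -2.11 ± 0.50 (adjusted p = 0.0182) and -1.87 ± 0.34 (adjusted p = 0.00127), and Tnfrsf9 was -1.56 ± 0.41 (adjusted p = 0.0408). Cxcr3 was -1.24 ± 0.23 (adjusted p = 0.00145), Fos -1.12 ± 0.18 (adjusted p = 0.000213) and Klf2 -1.41 ± 0.33 (adjusted p = 0.0183, limma-voom 0.103). Lower too were Vps37b, an endosomal sorting gene, at -1.60 ± 0.28 (adjusted p = 0.000765, limma-voom 0.0673) and Cxcr5 at -4.29 ± 0.91 (adjusted p = 0.0056). The ratio of mean Cxcr5 CPM, HDM over naive, was 0.806 on secondary and 0.191 on tertiary days, a smaller change than the fitted fold. Cd69 (0.36 ± 0.24, adjusted p = 0.789) and Tnfsf8 (0.37 ± 0.64, adjusted p = 1) missed the threshold, though both passed without day 45 naive CD69+ replicate 1 (0.65, adjusted p = 0.0267, and 3.47, adjusted p = 5.41e-05).

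Mitochondrially encoded genes of the respiratory chain gained as well in HDM CD69+ cells, with mt-Nd5 at 1.96 ± 0.34 (adjusted p = 0.000584), mt-Nd6 at 1.95 ± 0.43 (adjusted p = 0.00902, 0.162 without a filter) and mt-Nd2 at 1.69 ± 0.36 (adjusted p = 0.00573). The mitochondrial share of counts in HDM CD69+ libraries was 2.49 ± 0.54% on secondary and 4.94 ± 1.52% on tertiary days, against 2.61 ± 0.60% and 2.6 ± 0.37% in naive libraries. On tertiary days HDM and naive libraries differed in this share (permutation test, two-sided, p = 0.00025, 0.002 after Benjamini-Hochberg adjustment over 16 tests), and on secondary days the test gave p = 0.48. The share of the 20 most counted genes also differed on tertiary days, at 16.7% in HDM and 12.7% in naive CD69+ libraries (0.0092 after the same adjustment) and 16.9% and 13.1% in CD69- libraries (0.0041). Rn18s-rs5, a ribosomal RNA gene, took up to 4.86% of counts (day 47 HDM CD69- replicate 1). Altogether 131 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (61 higher, 70 lower), and 100 when tested and adjusted among genes with at least 1 count in every compared group (63 higher, 37 lower). DESeq2 called 1304 and limma-voom 612. Recirculation genes had 3 of 16 lower (9 adjusted over the list alone, adjusted p = 0.00081 with an estimated correlation) and costimulatory genes 3 of 14 lower (6 adjusted over the list alone, adjusted p = 0.028 with an estimated correlation). The regulatory list had 1 of 16 higher and 2 lower (1 and 6 adjusted over the list alone, adjusted p = 0.04 with an estimated correlation). Day and response were confounded, since each day belonged to a single response. Splits of the 8 days that mixed the responses gave up to 168 genes. Without day 45 naive CD69+ replicate 1 the count was 2576 and Cxcr5 stood at -1.17 (adjusted p = 1). Without day 47 HDM CD69+ replicate 3 it was 199, and it was 74 to 87 without day 22 naive CD69+ replicate 1 or 2, day 23 replicate 2, day 24 replicate 1 or 2, day 47 replicate 1 or day 48 replicate 1. Tnfrsf9 missed the threshold in 19, Klf2 in 4 and Foxp3 in 2 of the 40 fits that left out 1 library.

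**Figure D4:**
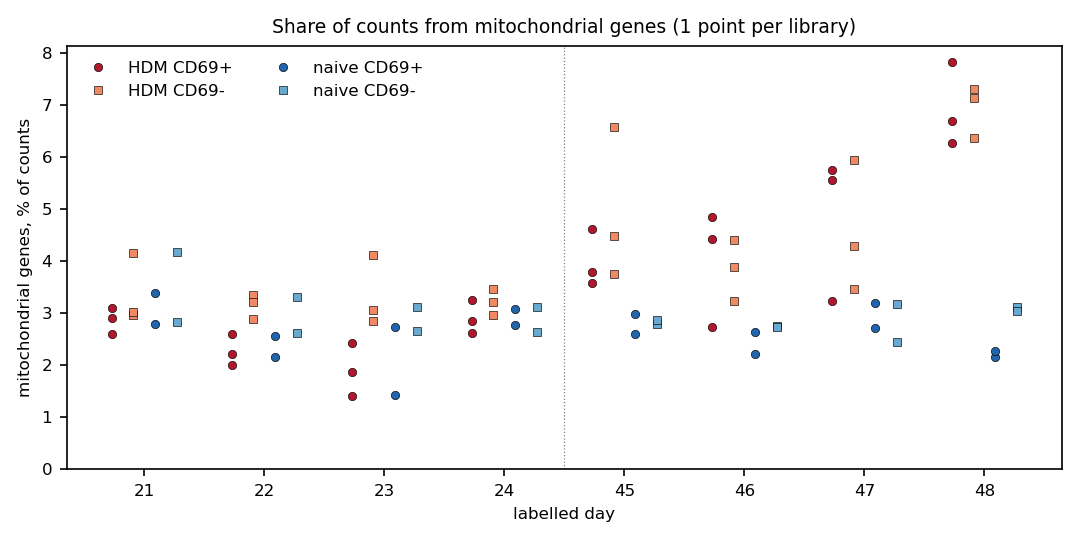
Share of counts from mitochondrially encoded genes, in percent, in each library by day, gate and mouse status. HDM CD69+ libraries averaged 2.49% on days 21 to 24 and 4.94% on days 45 to 48, and naive CD69+ libraries 2.61% and 2.6%.

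In CD69- cells the change of the HDM difference between responses was called for 12 genes (6 higher, 6 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 633 by DESeq2. Rgs1 gained 1.98 ± 0.26 (adjusted p = 6.4e-06) and Fgl2 2.11 ± 0.41 (adjusted p = 0.00804). The mitochondrial genes mt-Nd4 and mt-Cytb gained 1.36 ± 0.31 (adjusted p = 0.0487) and 1.28 ± 0.27 (adjusted p = 0.022), and Psma7, a proteasome gene, 0.76 ± 0.16 (adjusted p = 0.0216). Cd27 was -2.28 ± 0.41 (HDM libraries 370 ± 131 CPM on secondary and 100 ± 73.4 CPM on tertiary days, adjusted p = 0.00303), Gimap3, a lymphocyte survival gene, -1.17 ± 0.17 (adjusted p = 3.2e-05) and Cxcr3 -1.26 ± 0.23 (adjusted p = 0.00303). Malat1 was -1.53 ± 0.31 (adjusted p = 0.0128), Vps37b -1.25 ± 0.28 (adjusted p = 0.0468) and Fos -1.01 ± 0.18 (adjusted p = 0.00251). Tnfrsf4 (0.32 ± 0.23, adjusted p = 1) and Icos (-0.56 ± 0.22, adjusted p = 0.48) missed the threshold. Type 2 genes passed as a list, with 0 of 18 past the threshold over all genes tested and 2 higher adjusted over the list alone (adjusted p = 0.027 with an estimated correlation). With limma-voom the adjusted p was 0.761 for Rgs1, 0.167 for Fgl2, 0.979 for mt-Cytb, 0.0874 for mt-Nd4, 0.0752 for Psma7, 0.182 for Malat1, 0.168 for Vps37b and 0.0806 for Fos. Without subtraction of naive libraries Vps37b was -0.45 (adjusted p = 0.184) and Fos -0.31 (adjusted p = 0.14), so much of both differences came from the naive libraries. In the 40 fits that left out 1 library, Vps37b missed the threshold in 28, mt-Nd4 in 26, mt-Cytb in 11, Psma7 in 6 and Malat1 in 2. The count was 168 without day 45 naive CD69- replicate 1, 20 without day 45 HDM CD69- replicate 2, and 6 without day 21 naive CD69- replicate 1. It was 7 without day 45 HDM CD69- replicate 3, day 45 naive CD69- replicate 2 or day 48 naive CD69- replicate 2.

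Tests within single days, with 3 HDM and 2 naive CD69+ libraries each, called few genes on secondary days in edgeR. On day 21 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 577 at an unadjusted p under 0.05, 455 called by DESeq2 and 81 by limma-voom. EdgeR called 5, 20 and 12 on days 22, 23 and 24, and 170, 221, 128 and 235 on days 45, 46, 47 and 48. DESeq2 and limma-voom both called more than edgeR on days 22 to 24, and limma-voom called more on day 23 than on days 46 and 47. In simulations at this size, 7% of genes with a change of 4-fold were recovered. Ifi27l2a was 2.48 higher on day 23 (adjusted p = 4.49e-05), 3.26 higher on day 24 (adjusted p = 1.98e-07) and 3.0 higher on day 48 (adjusted p = 5.31e-07), and -1.58 on day 45 (adjusted p = 0.00593). Rgs1 was 3.19 higher on day 47 (4560 ± 518 CPM in HDM libraries, adjusted p = 1.62e-06) and 2.83 on day 48 (6570 ± 628 CPM, adjusted p = 1.69e-05). Tnfrsf4 was 1.55 higher on day 23 (adjusted p = 0.0301) and 1.63 on day 24 (adjusted p = 0.0218), -1.85 on day 45 (275 ± 139 against 988 ± 223 CPM, adjusted p = 0.000915) and 1.65 higher on day 46 (adjusted p = 0.00286). Without the 3 libraries with few detected genes, of which 2 were in this test, the day 45 count was 17, from 2 HDM libraries and 1 naive library. The libraries labelled day 46 carry titles that read day 45. Leaving out 1 library gave 3 genes without naive replicate 2 and 45 without naive replicate 1 on day 23, and 2 without naive replicate 2 on day 24. It gave 30 without naive replicate 2 and 4254 without naive replicate 1 on day 45, and 46, 16 and 48 without naive replicate 1 on days 46, 47 and 48. Scaling by RLE factors changed the day 47 split from 81 higher and 47 lower to 55 and 70, and that of day 48 from 128 and 107 to 116 and 130.

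**Figure D5:**
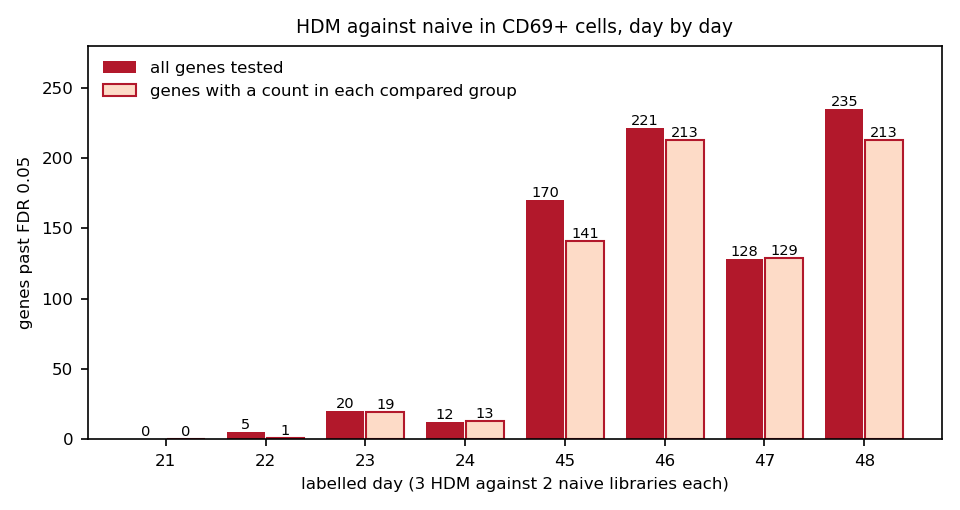
Number of genes called between 3 HDM and 2 naive CD69+ libraries on each day, among all genes tested and among genes with at least 1 count in each compared group. Bars reach 20 genes at most on days 21 to 24 and lie between 128 and 235 for all genes on days 45 to 48.

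Between days 21 and 24 the HDM difference in CD69+ cells changed for 8 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (6 higher, 2 lower), against 761 by DESeq2 and 65 by limma-voom. Ifi27l2a gained 3.06 ± 0.48 (adjusted p = 0.000592), Ly6a, an interferon-induced surface gene, 2.10 ± 0.43 (adjusted p = 0.0236, limma-voom 0.351) and H2-T23, a class Ib antigen-presenting gene, 2.19 ± 0.43 (adjusted p = 0.0155). Npc2, a lysosomal cholesterol gene, gained 1.78 ± 0.39 (adjusted p = 0.0484, 0.155 without a filter and 0.0688 with filterByExpr) and Actg1, an actin gene, 1.37 ± 0.23 (adjusted p = 0.00166). Fos was -1.87 ± 0.36 (adjusted p = 0.0129) and Tsc22d3, a glucocorticoid-induced gene, -1.73 ± 0.34 (adjusted p = 0.013). Tnfrsf4 missed the threshold (0.74 ± 0.46, adjusted p = 0.869). Without day 24 HDM replicate 1 the count was 15, without day 24 HDM replicate 2 or naive replicate 2 it was 3, and without day 21 HDM replicate 3 or day 24 naive replicate 1 it was 5. Ifi27l2a (limma-voom 0.68) and Actg1 (limma-voom 0.692) alone among those named held in each such fit.

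From day 45 to day 48 the HDM difference changed for 71 genes by the same test (41 higher, 30 lower), and from day 21 to day 45 for 20 (12 higher, 8 lower). Ifi27l2a gained 4.58 ± 0.50 between days 45 and 48 (adjusted p = 1.36e-08, limma-voom 0.279). Tnfrsf4 gained 2.20 ± 0.46 between these days (adjusted p = 0.0127, limma-voom 0.201, lost in 3 of the 10 fits that left out 1 library) and was -2.74 ± 0.47 between days 21 and 45 (adjusted p = 0.00182, limma-voom 0.0683). Lag3, an inhibitory receptor gene, was at 7.87 ± 7.55 CPM in HDM libraries of day 45 and 434 ± 126 CPM on day 48, and at 131 ± 186 and 109 ± 28.9 CPM in naive libraries (adjusted p = 0.0377, limma-voom 0.66). Between days 21 and 45 Izumo1r was -4.02 ± 0.71 (adjusted p = 0.00182), and Tox2, a follicular helper gene, -5.81 ± 1.27 (adjusted p = 0.0229), though Tox2 missed the threshold in 4, Izumo1r in 1 and Tnfrsf4 in 1 of the 10 fits that left out 1 library. Cxcr5 passed too (adjusted p = 0.00845), at 133 ± 24.7 CPM in HDM and 43.8 ± 25.8 CPM in naive libraries on day 21, and 0.0953 ± 0.165 and 109 ± 155 CPM on day 45. The median of all genes with a mean log2 CPM of at least 3 was -0.52 between days 45 and 48 and 0.34 between days 21 and 45. Without the 3 libraries with few detected genes the counts were 13 and 13, and Tnfrsf4 gained 1.58 from day 45 to 48 (adjusted p = 0.193). Without day 45 naive CD69+ replicate 1 alone they were 4131 and 3757, with Lag3 at -6.69 and Cxcr5 at 0.96. The day 45 to 48 count was 167 without day 45 HDM replicate 3 and 12 to 14 without day 45 naive replicate 2 or either naive replicate of day 48. The day 21 to 45 count was 100 and 34 without day 45 HDM replicate 3 and 2, 12 and 13 without day 21 naive replicate 2 and 1, and 6 without day 45 naive replicate 2.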

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

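Of the tests below, the one on the mitochondrial share in naive libraries and the one on epithelial RNA were chosen after the result was seen. Differences between groups that passed a test of the difference itself are listed here, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No group had 4 or more replicates, so no test for a single library far from its own group was run.

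The gene count that changed between the secondary and the tertiary HDM response was 131 in CD69+ and 12 in CD69- cells, and 4 of 35 and 6 of 35 splits of the 8 days into 4 and 4 gave as many. Chance assignment of the days therefore cannot be excluded. The highest counts of other splits were 168 and 38, both for days 21, 22, 23 and 45 against the rest, which points to a structure among the days that the response does not describe. Rgs1 (1.66), Fgl2 (2.05), Il7r (1.74), Cxcr6 (1.58) and Maf (1.42) gained in CD69+ cells. Among receptors and regulatory genes, Tnfrsf4 (-1.07), Icos (-0.97), Tnfrsf9 (-1.56), Foxp3 (-2.11), Izumo1r (-1.87), Cxcr5 (-4.29) and Cxcr3 (-1.24) were lower, Tnfrsf4 mostly through day 45, as were Fos (-1.12), Klf2 (-1.41) and Vps37b (-1.60). For Cxcr5 the ratio of mean CPM, HDM over naive, went from 0.806 on secondary to 0.191 on tertiary days. That change is smaller than its fitted fold, which is not a measure of size. Fgl2 (2.11), Rgs1 (1.98) and Psma7 (0.76) gained in CD69- cells, where Cd27 (-2.28), Malat1 (-1.53), Cxcr3 (-1.26), Vps37b (-1.25), Gimap3 (-1.17) and Fos (-1.01) were lower.

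Mitochondrially encoded genes formed the first pattern that was weighed. In CD69+ cells mt-Nd5 (1.96), mt-Nd6 (1.95) and mt-Nd2 (1.69) gained in the tertiary HDM difference, and in CD69- cells mt-Nd4 (1.36) and mt-Cytb (1.28). Over the 12 protein genes the median was 1.63 with an SD of 0.58, and 6 passed. A lower number of detected genes, the 3 libraries with few of them and a change of all libraries were argued against as the whole cause. With the number of detected genes in the model the median was 1.69, and without the 3 libraries with few detected genes it was 1.53. The mitochondrial share of naive CD69+ libraries changed by -0.018 points on the tertiary days against 2.46 points in HDM libraries, so a change of all libraries made on those days cannot be the whole cause. The share of the 20 most counted genes rose in the same libraries (16.7% against 12.7% in naive ones on tertiary days). A difference in library composition, cell stress or handling limited to HDM lungs, or a higher mitochondrial content of T cells recalled a further time, may underlie the pattern and was not tested.

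The count of genes that differed between HDM and naive CD69+ cells on single days formed the second pattern, with 37 calls over the secondary and 754 over the tertiary days in edgeR. These counts, and the thinned ones below, kept the day 45 libraries with few detected genes. Without those libraries the day 45 test rests on a single naive library, so that day's part in the gap cannot be settled. The size of the gap between the responses depended on the test, and in limma-voom not every tertiary day lay above every secondary day. DESeq2 also called more genes on each tertiary than on each secondary day, but by a smaller ratio. Limma-voom called more on day 23 than on days 46 and 47, and most of its tertiary calls fell on day 45. Sequencing depth was argued against, since thinning each library to 890699 counts gave 40 and 720 calls, a ratio of 18. The median SD within groups was 0.572 on tertiary and 0.495 on secondary days, a ratio of 1.16. The spread was thus not smaller on tertiary days. The tests of all days shared a common estimate of the spread per gene, so a day's own spread did not set its error. This comparison therefore cannot decide whether spread shaped the counts, and an effect of the larger spread was not tested. A larger HDM effect on the tertiary days remains open. The median difference of 348 genes called in CD69- cells was 0.0582, 0.42, 0.382 and 0.58 on days 21 to 24. It was 0.402, 0.921, 0.839 and 1.14 on days 45 to 48, so days 46, 47 and 48 lay above each secondary day. Day 45 lay at 0.693 of the highest secondary day. Its median SD within groups was 2.36, against 0.42 to 0.611 on the other days. The responses thus overlapped through day 45, and each day came from its own libraries.

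Pxdc1, Ramp1, Il17rb, Sdc1, Blk and Il1r1, all highest in naive CD69- libraries, formed the third pattern. Their summed level was 1080 ± 467 CPM there, against 429 ± 126 in naive CD69+, 469 ± 179 in HDM CD69+ and 323 ± 167 in HDM CD69- libraries. Epithelial RNA remains open. The 6 genes reached 39.6% of that level in naive CD69+ libraries, but the epithelial transcript Sftpc varied too much between libraries to decide (170 ± 274 CPM there against 83.7 ± 110 in naive CD69-). Gamma delta T cells remain open as well. The 6 genes had a ratio of 2.66, but were chosen for being highest in these libraries, so that ratio sets no mark for other genes. Summed, the receptor genes of gamma delta T cells were 1.69 times the mean of the other kinds of library in naive CD69- libraries (176 ± 76.7 CPM, permutation p = 0.00015). The excess lay in Tcrg-C1, Tcrg-C4 and Tcrg-V4, while Trdc, the delta constant gene, was at 2.19 CPM in naive CD69- and 6.18 CPM in HDM CD69+ libraries, and the list did not pass between gates in naive mice (p = 0.37 with an estimated correlation) but was lower in HDM than in naive CD69- cells (p = 0.019), where Tcrg-C1 (adjusted p = 0.0248) and Tcrg-V4 (adjusted p = 0.0257) passed. A CD4 gate would remove such cells but is not stated in the labels. Invariant NKT cells remain open, as their receptor genes Trav11 and Trav11d had a ratio of 2.92 (permutation p = 0.029) but averaged 0.625 reads per naive CD69- library and were at 0 in 65 of 80 libraries.

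The CD69 difference itself differed between HDM and naive mice for 10 genes. Pxdc1 (2.45) and Ramp1 (1.48) were higher in HDM mice, and Malat1 (-0.99), Rnf125 (-0.83), Akap13 (-0.79), Ptpn22 (-0.72), H2-Q6 (-0.57) and Gimap3 (-0.54) lower. Of these, Ramp1 alone held in each fit that left out 1 library and alone passed with an additive day term. Of 100 regroupings of the libraries within each day, the real one included, 34 gave at least 10 genes and the highest other gave 113. Chance therefore cannot be excluded for the count, and a count that high points to a structure of the libraries. Whether the day 45 libraries with few detected genes gave it was not tested.

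The HDM difference in CD69+ cells changed for 8 genes from day 21 to 24, with Ifi27l2a (3.06), H2-T23 (2.19), Ly6a (2.10), Npc2 (1.78) and Actg1 (1.37) higher and Fos (-1.87) and Tsc22d3 (-1.73) lower. From day 45 to 48 it changed for 71 genes, among them Ifi27l2a (4.58), Tnfrsf4 (2.20) and Lag3 (6.05), and from day 21 to 45 for 20, among them Tnfrsf4 (-2.74), Izumo1r (-4.02), Cxcr5 (-11.53) and Tox2 (-5.81). The fitted folds of Lag3 and Cxcr5 rest on libraries near 0 CPM and ran from -6.69 to 7.05 and from -14.08 to 0.96 when 1 library was left out, so neither is a measure of size.

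Regroupings of the libraries within each day also tested the other counts. For CD69+ against CD69- cells in HDM mice the real value of 497 (with the shared dispersion trend) was reached by 1 of 100, itself. The highest other was 6, so chance regrouping is argued against. In naive mice the real value of 238 was likewise reached by 1 of 100, with 188 as the highest other, which points to a structure of the libraries. For HDM against naive in CD69- cells the count of 437 was reached by 1 of 100, itself, with 2 as the highest other. Chance regrouping is argued against there too. In CD69+ cells the count of 1038 was reached by 3 of 100, with 1576 as the highest other. That share lies under 0.05, but a regrouping exceeded the real count, so chance is not excluded for its size. A regrouping that calls 1576 genes points to a structure of the CD69+ libraries other than HDM status. The regroupings also moved the day 45 libraries with few detected genes between groups. Whether these libraries gave the counts of 188 and 1576 was not tested.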

How the results depend on the processing

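Fits without the 3 libraries with few detected genes, without genes at 0 in a compared group, with an additive day term and with detected genes as a covariate were chosen after seeing the data, and the others were planned. Unless a construction is named, the cause was not tested.

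The text names 75 different genes in 143 gene and comparison pairs, of which 130 passed the threshold. Under the settings other than leaving out 1 library, the pairs gave 2243 values, of which 2047 kept their direction and side of the threshold, 174 no longer passed, 22 newly passed and 0 changed sign. With 1 library left out they gave 5638 values, of which 5041 kept both, 586 no longer passed, 8 newly passed and 3 changed sign.

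Counts moved by over 1.5 times under these settings. DESeq2 called 1630 (CD69+ against CD69- in HDM mice), 1050 (naive mice), 765 (their difference), 2464 (HDM against naive, CD69+), 1304 (CD69-), 1304 and 633 (tertiary against secondary, CD69+ and CD69-), 761, 1661 and 1235 (days 24 against 21, 48 against 45, 45 against 21), and 455, 239, 688, 713, 1805, 1170, 1015 and 1207 on days 21 to 24 and 45 to 48. Limma-voom called, in the same order, 1028, 974, 111, 2475, 867, 612 (CD69+), 65, 1885, 1844, and 81, 32, 881, 153, 2903, 622 and 272 on days 21 to 47. In limma-voom several genes of high counts lost their calls, such as Rgs1, whose adjusted p in HDM against naive CD69+ cells was 0.139.

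With an absolute log2 fold change of at least 1 the first 5 counts were 266, 99, 3, 486 and 169, by a stricter threshold. Without a filter, on 24131 genes in place of 13508, they were 49 (difference of the CD69 contrasts), 289 and 104 (tertiary against secondary), 39, 188 and 105 (between days) and 7, 11, 59, 76 and 302 (days 21, 22, 23, 24 and 45). The filterByExpr filter gave 4 (difference of the CD69 contrasts) and 46 (day 48 against 45), and RLE factors 5 for that difference. RLE factors shifted the median of all genes against TMM by over 0.1 in 3 comparisons, by -0.133 for day 48 against 45, -0.159 on day 47 and -0.133 on day 48.

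Without the 3 libraries with few detected genes the counts were 14, 13 and 13 between days and 1, 48, 57, 17, 434, 297 and 429 on days 21, 23, 24, 45, 46, 47 and 48. Without genes at 0 in every library of a compared group, fewer genes were tested and 303 (CD69 in HDM mice) and 1 (day 22) passed. The detected genes as a covariate gave 21 for tertiary against secondary in CD69- cells. The block for consecutive title numbers gave 2474, 878 and 608 for HDM against naive in CD69+ and CD69- cells and for tertiary against secondary in CD69+ cells, close to limma-voom, in which it was fitted. Consecutive numbers correlated with a median r of 0.0178 over 40 pairs, against -0.00754 for other pairs of the same day and status. Of the 40 CD69+ libraries, 31 correlated best with the consecutive number. Each had 3 candidates in HDM and 2 in naive mice, so chance would match fewer than that. Consecutive libraries were therefore more alike than other pairs, though weakly. Whether they came from the same mice is not stated, and the main tests treated the gates as independent libraries. Fits to the compared groups alone gave 668 and 784 for HDM against naive in CD69+ and CD69- cells. Without subtraction of naive libraries, a comparison of HDM libraries alone, 1012 and 383 (tertiary against secondary), 51, 294 and 136 (between days) passed.

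Leaving out a day gave 2, 4, 2, 1, 24, 2, 2 and 1 genes for the difference of the CD69 contrasts (days 21 to 24 and 45 to 48), 663 for HDM against naive CD69+ cells (day 48), and 659, 231, 241 and 186 for CD69- cells (days 45 to 48). Of the 84 list tests past the threshold, 36 passed with an estimated correlation.

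Leaving out 1 library gave these ranges: 384 to 629 (CD69 in HDM mice), 175 to 2763 (naive mice), 1 to 1613 (their difference), 815 to 3218 and 308 to 700 (HDM against naive, CD69+ and CD69-), 74 to 2576 and 6 to 168 (tertiary against secondary), 3 to 15, 12 to 4131 and 6 to 3757 (days 24 against 21, 48 against 45, 45 against 21), and 0 to 5, 1 to 6, 3 to 45, 2 to 15, 30 to 4254, 46 to 213, 16 to 271 and 48 to 171 on the 8 days. The correlation between the CD69 differences ran from 0.19 to 0.34. The highest counts of 2763, 1613, 3218, 2576, 4131, 3757 and 4254 came without day 45 naive CD69+ replicate 1, which leaves a library of 5213 detected genes alone in its group. Without that library 3 named genes changed sign. Their ranges over all fits without 1 library were -0.93 to 1.59 for Tnfsf8 in naive mice, -6.69 to 7.05 for Lag3 from day 45 to 48 and -14.08 to 0.96 for Cxcr5 from day 21 to 45.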

Other observations

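The list tests within single days, given here, were chosen after the data were seen.

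Within single days, 18 lists were tested for HDM against naive libraries in both gates, 288 tests adjusted together with camera and an estimated correlation. Interferon response genes were higher in HDM CD69+ cells on day 23 (median log2 difference 2.54, 20 of 21 genes, adjusted p = 0.00057), day 24 (3.57, 21 of 21 genes, adjusted p = 7.1e-07) and day 48 (2.24, 19 genes, adjusted p = 0.0098), and their difference on day 21 was -0.17 (adjusted p = 0.93). In CD69- cells the list was higher on day 23 (2.50, adjusted p = 1.1e-06), day 24 (2.93, adjusted p = 7.1e-07), day 46 (2.11, adjusted p = 0.00063) and day 48 (2.03, adjusted p = 0.0035). Proliferation genes were higher on days 23 (1.57, adjusted p = 0.021) and 48 (1.26, adjusted p = 0.037) in CD69+ cells. In CD69- cells they were higher on days 23 (1.29, adjusted p = 0.023), 24 (1.54, adjusted p = 0.0036) and 48 (2.50, adjusted p = 0.0013). Type 2 genes were higher in CD69+ cells on day 22 (1.82, adjusted p = 4.7e-05), day 23 (1.75, adjusted p = 0.0014), day 24 (1.53, adjusted p = 0.0035), day 47 (1.67, adjusted p = 0.0089) and day 48 (1.55, adjusted p = 0.042), and in CD69- cells on day 45 (3.21, adjusted p = 0.0035), day 46 (1.22, adjusted p = 0.044) and day 47 (1.52, adjusted p = 9e-04). Heat shock genes were higher on day 22 in CD69+ (0.61, adjusted p = 0.017) and CD69- cells (0.56, adjusted p = 0.018). Follicular helper genes were lower on day 45 in CD69+ (-1.17, adjusted p = 0.023) and CD69- cells (-2.35, adjusted p = 0.00021), the day of the 3 libraries with few detected genes, and higher on day 24 in CD69- cells (0.47, adjusted p = 0.042). Immediate early genes were lower on day 48 in CD69+ (-1.43, adjusted p = 0.0029) and CD69- cells (-1.13, adjusted p = 0.0013). Recirculation genes were lower on day 47 in CD69+ (-1.91, adjusted p = 0.0092) and on day 45 in CD69- cells (-1.59, adjusted p = 0.027), and type 1 and cytotoxic genes on day 45 in CD69- cells (-2.16, adjusted p = 0.0073). Glycolysis genes were higher in CD69+ cells on days 23 (0.93, adjusted p = 0.0098) and 46 (0.70, adjusted p = 0.01), and regulatory genes on day 24 in CD69+ (0.25, adjusted p = 0.041) and CD69- cells (1.32, adjusted p = 0.0029). The 6 genes of the title were higher in CD69+ cells on day 24 (1.89, adjusted p = 0.01). A single day is a single set of libraries, so day and batch cannot be told apart in these values.

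Cd8a, a marker of CD8 T cells, had 0 counts in each of the 80 libraries, while Cd8b1 averaged 12 ± 9.79 CPM and Cd4 553 ± 134 CPM in HDM CD69+ libraries. Since Cd8b1 was counted, the 0 of Cd8a cannot be taken as absence of CD8 T cells.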
